A study of Homo sapiens with 3 samples.

How the data were processed

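Expression was measured in MDA-MB-231 cells, an established human breast cancer line, on Affymetrix HG-U133 Plus 2 arrays with 54675 probe sets. Per the labels' protocols, cells were kept for 4 h in medium with 10% charcoal-stripped serum, which is low in steroids, and were then treated for 3 h. There was 1 array for each of 3 groups: vehicle (0.1% ethanol), estradiol at 1 µM and ERα17p at 1 µM. ERα17p is a peptide derived from the oestrogen receptor alpha. The series title speaks of a time course, and the arrays analysed here hold 1 time point. Total RNA was labelled with biotin by the Affymetrix protocol, per the labels.

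RMA (background correction, quantile normalisation and summary of probes into probe sets on a log2 scale) is named in the submitters' processing notes, with no version. The deposited values are taken as log2 values because RMA gives that scale; the base of the logarithm is not given in the sources used here. The deposited values had also been centred probe set by probe set on a reference level that no source describes: every array had a median of 0, and 7.08%, 8.14% and 8.54% of probe sets were exactly 0 on the vehicle, estradiol and ERα17p arrays. Since most probe sets had no exact 0 on any of the 3 arrays, their median cannot have been the reference. Exact zeros on each array would arise from a median over a larger set of arrays that held all 3, but no source states this. The centring removes each gene's expression level and leaves differences between arrays untouched. No level, signal over background or detection call can therefore be given, and a difference may belong to a gene near the detection limit.

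The groups, alternatives, 25 gene lists and rule for naming genes were fixed before the data were examined. The centring made 2 planned settings impossible, an expression limit and the choice of the probe set with the highest mean per gene. After the data were seen, 2 other settings already listed took their place: no expression limit, and the median of each gene's probe sets. Random gene lists could not be matched on expression and were matched on the number of probe sets per gene.

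Gene symbols came from the platform's annotation. Of the probe sets, 41097 were paired with 1 symbol, 1801 with several and 11777 were unnamed; those with several were not used. This gave 19775 genes, of which 9252 had 1 probe set and 10523 had 2 or more. The Entrez identifiers of 19734 genes were found in the RefSeq gene table of GRCh38.p14, used for names only, and 0 symbols differed. No genome coordinates were used.

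For each gene the log2 difference between 2 arrays was taken. With 1 array per group there is no test and no p-value, and the number of arrays limits the precision. A gene was called higher or lower at a difference of at least 2-fold, and a list member at 1.5-fold. Lists with at least 5 measured members were described by their median difference and its percentile among 10000 random lists of the same size; a list stood apart when its median lay outside the central 95% of these. The percentile describes these arrays and is no test of a treatment. The lists were immediate early genes, growth factor feedback regulators, oestrogen receptors and co-regulators, classical oestrogen-induced genes, apoptosis promoters, apoptosis inhibitors, actin cytoskeleton and motility, extracellular matrix with proteases and adhesion, inflammatory NF-kB targets, interferon-stimulated genes, DNA replication and G1/S, mitosis and G2/M, p53 targets and cell cycle inhibitors, unfolded protein and integrated stress response, heat shock and chaperones, oxidative stress and metal response, cholesterol synthesis, hypoxia and glycolysis, TGF-beta targets, ribosomal proteins, replication-dependent histones, and markers of luminal breast epithelium, mesenchymal-like breast lines, blood cells, and fibroblasts and endothelium.

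Named genes were the 12 with the largest difference in each direction for the comparisons with vehicle, and 5 in each direction for the direct comparison, among genes whose probe sets all differed in 1 direction. Up to 4 members per list, those with the largest absolute difference, were named too, and ESR1, ESR2 and GPER1 always. Genes named outside this rule are marked as chosen after their values were seen.

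Technical spread was taken from control probe sets: labelling spikes (dap, lys, phe, thr and trp), hybridisation spikes (bioB, bioC, bioD and cre), 18S ribosomal RNA, and the 3' and 5' probe sets of ACTB and GAPDH. The correlation of the treatments' differences from the same vehicle array was set beside 100 draws of simulated unchanged arrays of equal spread and, added after seeing the data, 100 draws in which each array's gene values were shuffled over genes. The scripts were tested on simulated data, whose noise in every comparison was the shuffled difference between the treated arrays; the vehicle array spread more widely. Of 100 genes shifted by a log2 difference of 1.5, 97% were recovered past 2-fold for estradiol minus vehicle, 98% for ERα17p minus vehicle and 97% for ERα17p minus estradiol, each among 19775 genes. A shift of 2.5 was recovered in 100% for each.

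Alternatives were other size thresholds, the mean of a gene's probe sets, leaving out probe sets designed to match several transcripts (suffixes _s_at and _x_at), quantile normalisation of the deposited values, centring on array medians, and lists without their farthest member. Added after seeing the data were genes with 2 or more probe sets in 1 direction, the reference level in place of the vehicle array, unmatched random lists, and the percentile of each list under each alternative. The interferon-stimulated genes were also set against all 131072 assignments of signs to their own differences, by 3 statistics (mean, median and count of 1 sign), all 3 of which are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.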

Results

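Gene expression was compared after 3 h in MDA-MB-231 cells, a mesenchymal-like breast cancer line usually classed as negative for the oestrogen receptor alpha (ERα). The arrays were 1 of cells given 0.1% ethanol as vehicle, 1 of cells given 1 µM of the oestrogen estradiol, and 1 of cells given 1 µM ERα17p, a peptide derived from ERα. The design asks how each agent affects early gene expression, and how the peptide compares with the hormone. The solvent of the peptide is not given in the sources used here, so its comparisons may hold a solvent difference. There are no replicates, so no difference below has a replicate check, and each value describes these 3 arrays. All differences are log2 values computed from deposited values that had been centred per probe set on an undescribed reference, so expression levels are unknown.

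The vehicle array stood apart in RNAs that no treatment can alter. Labelling spikes, bacterial transcripts added to the RNA before labelling, were 2.03 higher on the estradiol array than on the vehicle array and 2.04 higher on the ERα17p array (medians of 27 probe sets, 4.08-fold and 4.10-fold). Between the treated arrays their median difference was 0.00. Of these spikes, trp differed little from vehicle, by 0.10 and 0.18, and the median of dap, lys, phe and thr was 2.14 and 2.10. Hybridisation spikes, added later, went the other way, at -0.74 and -0.93 (18 probe sets). The SD of the centred values was 0.494 on the vehicle array, 0.260 on the estradiol array and 0.241 on the ERα17p array. The 3' minus 5' value of ACTB was 0.11, -0.27 and 0.31 on the vehicle, estradiol and ERα17p arrays, and that of GAPDH was 0.13, 0.06 and 0.15. Each probe set was centred on its own reference, so a value near 0 does not show intact RNA. Only differences of these values between arrays bear on RNA integrity.

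**Figure D1:**
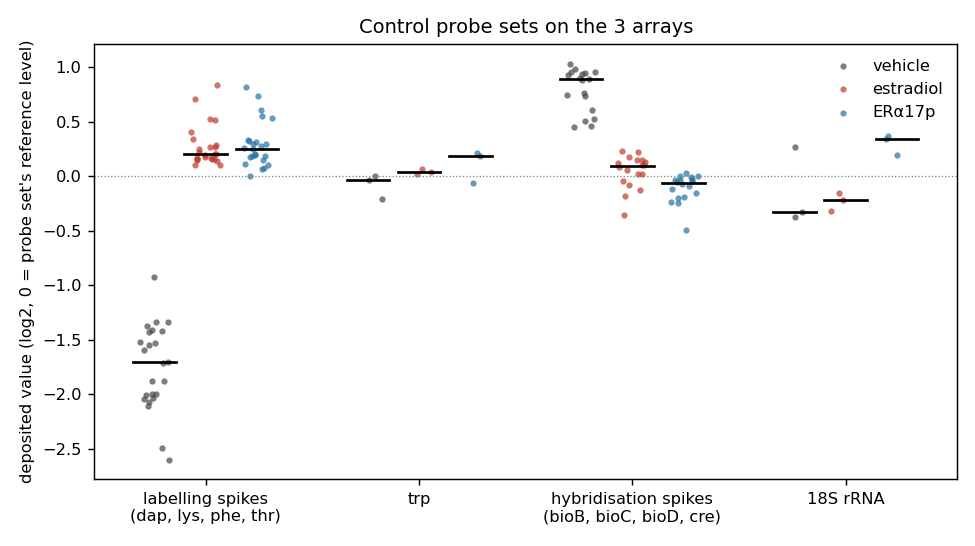
Deposited log2 value of each control probe set (points; bars are medians) on the vehicle, estradiol and ERα17p arrays, where 0 is the probe set's reference level. The labelling spikes dap, lys, phe and thr lie far lower on the vehicle array, by a median of 2.14 against estradiol, and the hybridisation spikes lie higher there.

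The largest differences of estradiol from vehicle were in TFF2, CST1 and HLA-DRA. TFF2, a secreted trefoil peptide of mucous epithelia, was 4.59 higher (24.1-fold). The cystatins CST1, CST2 and CST4, secreted inhibitors of cysteine proteases, were higher by 4.58, 3.37 and 3.33. HLA-DRA and HLA-DPA1, chains of MHC class II, were 4.56 and 4.29 higher, and the cytokine IL6 was 3.84 higher. CDH11, a cadherin of mesenchymal cells, was 4.11 higher, with its 4 probe sets between 1.91 and 7.04. The membrane protein gene MAL2 (4.29), COXFA4L3 (4.03), the retinol dehydrogenase SDR16C5 (3.93) and the ubiquitin ligase RNF128 (3.73) completed the 12 largest.

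Lower on the estradiol array were the immediate early genes EGR1 (-2.89, all 3 probe sets at -2.48 or below) and ARC (-2.52), and KISS1, which encodes the kisspeptin precursor (-3.32). The ribosomal protein gene RPL27A was at -3.49 and the splicing factor HNRNPA1 at -2.32; both have near-identical pseudogene copies, and with the pseudogene RPS16P5 (-2.45) their probe sets cannot be assigned with certainty. The non-coding LINC01296 (-3.51) and ASAP1-IT1 (-2.44), and LOC114224 (-2.55), FAM106A (-2.49), ZNF114 (-2.46) and LRRC20 (-2.31) made up the rest. In all, 779 genes were at least 2-fold higher and 432 at least 2-fold lower among 19775, or 514 and 196 after quantile normalisation. Against the deposited reference level in place of vehicle, 29 genes were higher and 1 lower on the estradiol array. That alternative was added after the data were seen. The full set of arrays behind the reference is unknown, and the exact zeros would arise if it held the treated arrays and the vehicle array. The smaller count therefore does not show how many calls come from the vehicle array.

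NF-kB targets and interferon-stimulated genes were the lists farthest above random lists for estradiol. Of 23 measured NF-kB targets, 11 were at least 1.5-fold higher and 4 lower, with a median of 0.51 (percentile 100 among random lists); IL6, the chemokine CXCL1 (2.99) and the adhesion molecule ICAM1 (2.77) led them. Of 17 interferon-stimulated genes 10 were higher and 1 lower, with a median of 0.67 (percentile 100); IFI27 was at 2.06, IFIT2 at 1.41 and IRF7, a factor of interferon induction, at -1.42. Hypoxia and glycolysis genes had 8 of 20 higher and 4 lower (median 0.46, percentile 99.99), with the glycolytic enzyme PGK1 at 1.94 and the angiogenic factor VEGFA at 1.72 and ADM at -1.92; with the mean of each gene's probe sets the median was 0.19, inside the random range. Growth factor feedback regulators had 7 of 15 higher and 0 lower (median 0.41, percentile 99.9), among them EREG (1.15), SPRED1 (1.14) and SPRY2 (1.08). Beside all of these the labelling spikes were 2.03 higher than on the vehicle array, and the hybridisation spikes were at -0.74. These classes went opposite ways, so they give no direction for a list.

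Cell cycle entry and immediate early genes lay on the low side. Of 20 DNA replication and G1/S genes 8 were at least 1.5-fold lower and 1 higher (median -0.42, percentile 0); the helicase subunits MCM5 and MCM7 were at -1.36 and -1.19, the licensing factor CDT1 at -1.27, and cyclin gene CCNE2 at 1.08. Immediate early genes had 10 of 32 lower and 5 higher (median -0.22, percentile 0.15), with FOSB at -1.70 beside EGR1, and with PTGS2 (2.64) and KLF4 (1.52) on the high side. Cholesterol synthesis had 4 of 14 lower and 0 higher (median -0.22, percentile 1.92), led by MVD (-0.87), and actin and motility genes 6 of 33 lower and 1 higher (median -0.13, percentile 2.06), led by ZYX (-1.28). These last 2 lists lay inside the central 95% of random lists not matched on probe set number. Cholesterol synthesis also lay inside it with the mean of probe sets (-0.17) and after quantile normalisation (-0.07). Hybridisation spikes were also lower on the estradiol array, at -0.74, while labelling spikes were higher, at 2.03.

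Smaller shifts upward were seen in matrix, stress and marker lists. Extracellular matrix, protease and adhesion genes had 10 of 26 higher and 2 lower (median 0.27, percentile 99.7), with the integrin ITGA2 at 1.65 and THBS1 at 1.39. The unfolded protein and integrated stress response had 6 of 20 higher and 1 lower (median 0.25, percentile 98.8), with VLDLR at 2.92 and the chaperone DNAJB9 at 2.00. Markers of mesenchymal-like breast lines had 5 of 15 higher and 0 lower (median 0.30, percentile 98.9), led by SNAI2 (1.84), and oxidative stress and metal response genes 1 of 14 higher and 0 lower (median 0.31, percentile 99.1), led by GCLM (0.86). Without probe sets that match several transcripts, the matrix list (0.01) and the stress response list (0.05) lay inside the random range. The oxidative stress list did too, but its median did not fall (0.32). Only 7 of its members were left, and the random range then reached 0.36. The stress response list also lay inside the range without its farthest member (0.20). Altogether 12 of 25 lists stood apart, and 6 of the 12 did under every alternative, a count chosen after the data were seen. For lists of unrelated genes 1.25 would stand apart. Members of a list can vary together and some lists share genes, so 1.25 is no exact chance expectation here.

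The largest differences of ERα17p from vehicle were in TFF2, CDH11 and HLA-DRA. TFF2 was 4.36 higher (20.5-fold), CDH11 4.35 higher with its probe sets between 2.20 and 7.28, HLA-DRA 4.12 higher and HLA-DPA1 4.09 higher. RNF128 (3.72), CST1 (3.68), IL6 (3.41), SDR16C5 (3.37) and MAL2 (3.34) followed. CYP1B1, a cytochrome P450 that hydroxylates estradiol, was 3.79 higher, although 1 of its 4 probe sets differed by 0.01 only. The tumour antigen gene MAGEC1 was 3.33 higher and AGR2, a protein disulphide isomerase of secretory epithelia, 3.31 higher.

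On the low side of the peptide's array were LOC730101 (-3.36), RPL27A (-3.34), KISS1 (-3.32), LINC01296 (-2.86), ZNF114 (-2.80) and MIR181A2HG (-2.62), the host transcript of a microRNA. EGR1 (-2.58), ARC (-2.46), the mitochondrial superoxide dismutase SOD2 (-2.42) and the adaptor subunit AP1M2 (-2.35) were also lower. RIMS2 (-2.60) and TAGLN (-2.44), an actin-binding protein of smooth muscle, had probe sets that ranged from -2.73 to -0.02 and from -3.91 to -0.42. In all, 661 genes were at least 2-fold higher and 491 at least 2-fold lower, or 397 and 295 after quantile normalisation. Against the reference level in place of vehicle, 3 were higher and 10 lower, with the same limit as for estradiol.

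Replication-dependent histones, whose main transcripts lack poly(A) tails, were the lowest list on the ERα17p array. Which transcript forms these probe sets read is not known. Of 10 measured, 8 were at least 1.5-fold lower and 0 higher, with a median of -1.08 (percentile 0); H1-2 was at -1.99, H2BC6 at -1.46 and H2AC6 at -1.27. Without probe sets that match several transcripts the histone median was -0.65. DNA replication and G1/S genes had 8 of 20 lower and 1 higher (median -0.36, percentile 0.01), with MCM5 at -1.44 and MCM2 at -1.38. Cholesterol synthesis had 6 of 14 lower and 0 higher (median -0.37, percentile 0.08), with FDPS at -0.86 and HMGCS1 at -0.76. Immediate early genes had 11 of 32 lower and 4 higher (median -0.22, percentile 0.15), with EGR1 the lowest and PTGS2 at 2.75. Mitosis and G2/M genes had 7 of 24 lower and 1 higher (median -0.22, percentile 0.53), led by the kinase AURKB (-1.55) and the proliferation marker MKI67 (-1.11); without its farthest member that list lay inside the random range. Beside these, hybridisation spikes were at -0.93 and labelling spikes at 2.04.

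Among lists on the high side for ERα17p, NF-kB targets had 9 of 23 at least 1.5-fold higher and 3 lower (median 0.48, percentile 100), with PTGS2 at 2.75 and CXCL1 at 2.66. Growth factor feedback regulators had 7 of 15 higher and 1 lower (median 0.42, percentile 99.96), with SPRY2 at 1.33 and EREG at 1.31. Hypoxia and glycolysis genes had 9 of 20 higher and 2 lower (median 0.37, percentile 99.93), with PGK1 at 2.00 and VEGFA at 1.86; with the mean of probe sets their median was 0.08, inside the random range. Markers of mesenchymal-like lines had 5 of 15 higher and 0 lower (median 0.26, percentile 98.6), led by SNAI2 (2.08). The stress response list had 8 of 20 higher and 2 lower (median 0.28, percentile 99.8), with VLDLR at 2.94, and the matrix list 7 of 26 higher and 2 lower (median 0.19, percentile 98.3), with ITGA2 at 1.66. Without probe sets that match several transcripts, the medians of these last 2 lists changed sign, to -0.09 and -0.01. Without their farthest members both lay inside the random range, at 0.10 and 0.12. The labelling spikes were 2.04 higher beside all of these, and the hybridisation spikes were at -0.93.

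Actin and motility genes (7 of 33 lower, 2 higher, median -0.12, percentile 2.46, ZYX at -1.30) and p53 targets (3 of 15 lower, 3 higher, median -0.22, percentile 2.18, SESN2 at -1.29) were at the edge of the random range. They lay inside it with unmatched random lists, after quantile normalisation and without their farthest member. That made 13 of 25 lists apart for ERα17p, of which 7 were apart under every alternative.

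**Figure D2:**
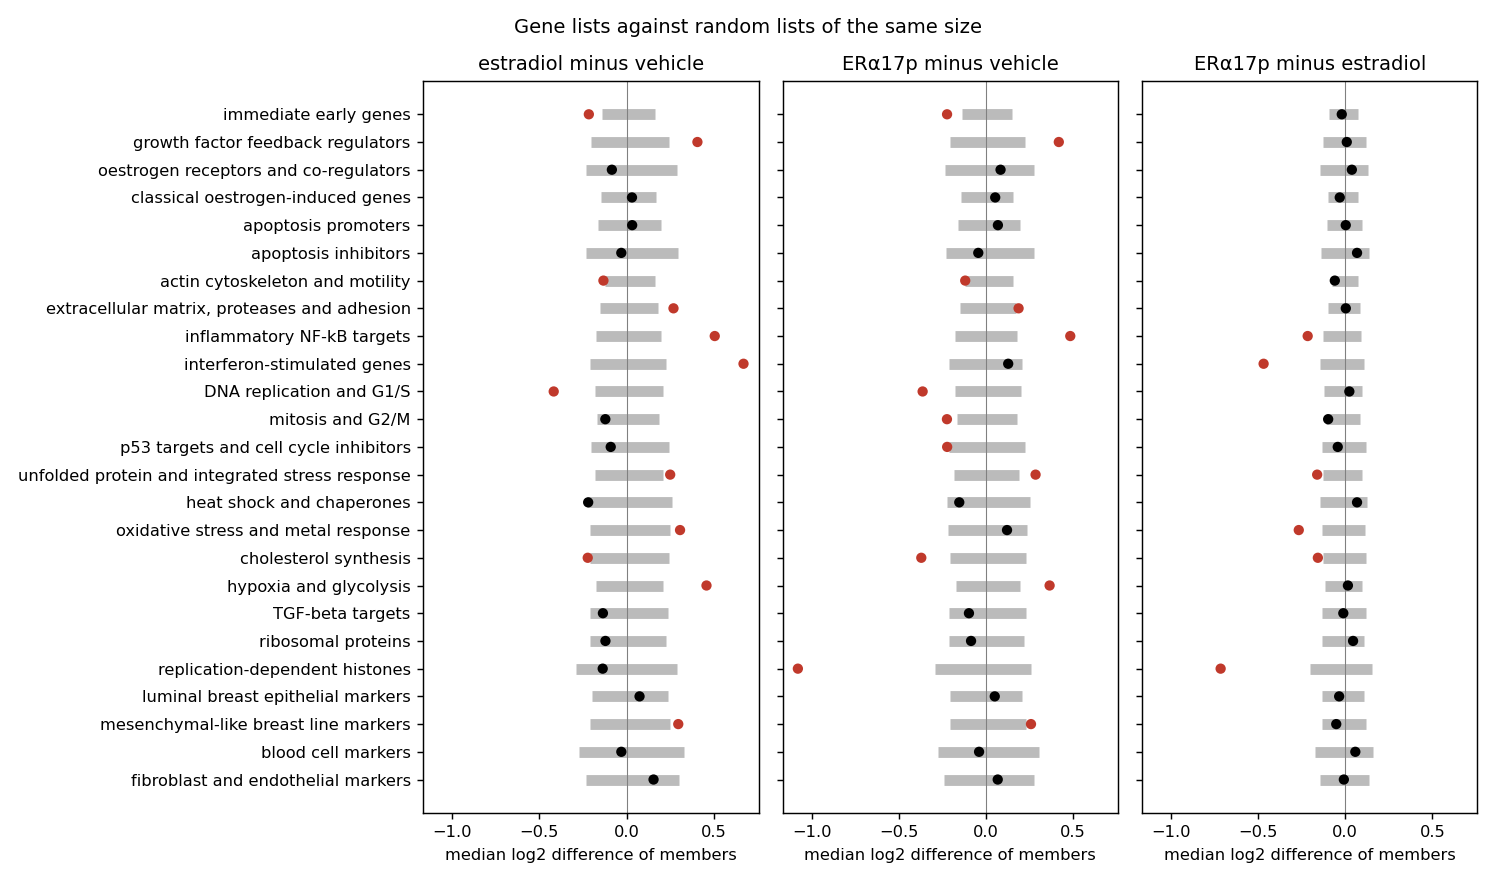
Median log2 difference of each gene list (points) in the 3 comparisons, with the central 95% of 10000 random lists as grey bars; red points lie outside it. Histones are at -1.08 for ERα17p minus vehicle and -0.72 for ERα17p minus estradiol, and interferon-stimulated genes at 0.67, 0.13 and -0.47.

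Both treatments shared most of their largest differences. Of the called genes, 547 were higher and 309 lower under both, including TFF2, IL6, KISS1 and EGR1. Across 19775 genes, which are not independent replicates, the differences from vehicle had a Pearson correlation of 0.871 and a Spearman correlation of 0.786. Both used the same vehicle array, which alone makes them correlate. Unrelated arrays, made after the data were seen by shuffling each array's values over genes so that it kept its own spread, gave correlations of 0.796 and 0.668, with 330 genes higher and 204 lower under both. Simulated arrays of equal spread gave 0.486 and 0.455, with 2.58 and 1.53 genes, but the vehicle array had the widest spread. The covariance was 0.231 observed, 0.162 with shuffled arrays and 0.0329 with equal spread. Only 1 vehicle array exists, so the controls could not be split, and most of the correlation may come from that array. After quantile normalisation the Pearson correlation was 0.717, and against the reference level in place of vehicle 0.228. In 558 of the 856 shared calls (65.2%), both treated arrays were within 1.5-fold of the reference and the vehicle array was at least 2-fold from it. The arrays behind the reference are unknown, so this does not place the difference on the vehicle array.

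**Figure D3:**
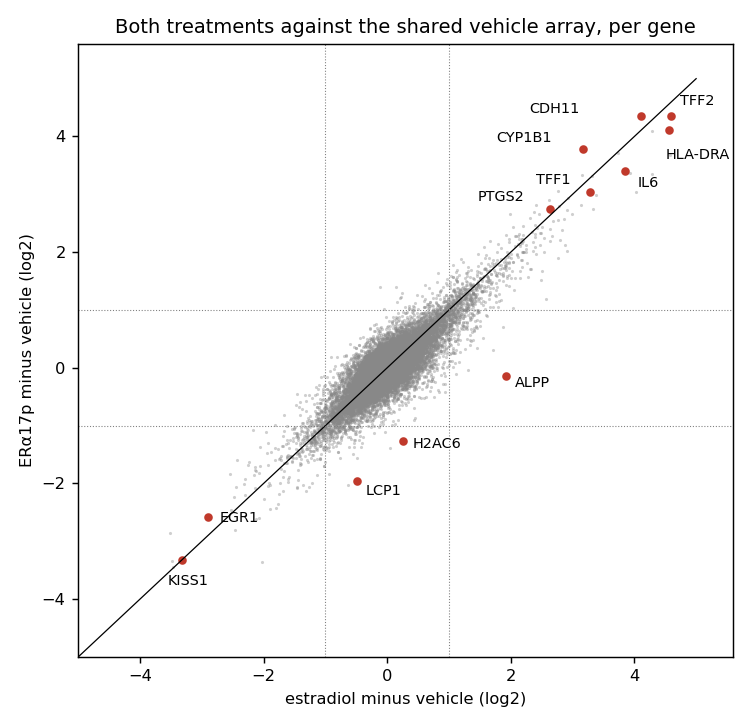
Log2 difference from vehicle for each of 19775 genes, estradiol on the x axis and ERα17p on the y axis; dotted lines mark 2-fold and the solid line equality. TFF2 (4.59 and 4.36) and KISS1 (-3.32 on both axes) lie far out near the diagonal, and ALPP, H2AC6 and LCP1 lie below it.

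Set directly against each other, which leaves the vehicle array out, the treated arrays differed in few genes. ALPP, placental alkaline phosphatase, was the lowest on the ERα17p array at -2.07, followed by TOLLIP-DT (-1.78), the histone H2AC6 (-1.53), the actin-bundling protein LCP1 (-1.46) and DLG1-AS1 (-1.43). SPDYA, an activator of cyclin-dependent kinases, was 1.52 higher, DCAF4L1 1.25 higher, the sterol transporter ABCG8 and AGAP4 both 1.09 higher, and MINAR1 1.07 higher. Each of these rests on 1 probe set. At least 2-fold, 7 genes were higher and 42 lower. In the simulated data, where these same differences were shuffled over probe sets, 43, 63 and 43 of 19575 unchanged genes passed 2-fold in separate draws. Shuffling keeps every large difference of a probe set, so these counts cannot tell whether the called genes differ from noise. Quantile normalisation of the deposited values gave 81 higher and 181 lower, and across 5015 genes with 2 probe sets the pair correlated at 0.0831, against 0.394 and 0.429 in the comparisons with vehicle.

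Histones and interferon-stimulated genes were the lists that differed most between the treatments. All 10 histones were lower on the ERα17p array, 8 by at least 1.5-fold (median -0.72, percentile 0), with H2AC6 lowest, then H2BC21 (-1.13) and H2BC5 (-0.89). Their median was -1.24 after quantile normalisation, which brings in the vehicle array's wider spread, and -0.50 without probe sets that match several transcripts. Of 17 interferon-stimulated genes 15 were lower, 4 by at least 1.5-fold (median -0.47, percentile 0), led by IFIT1 (-1.06) and by MX1 and OAS1 (both -0.75). The 18S ribosomal RNA was 0.53 higher on the ERα17p array, and the hybridisation spikes were at -0.15. The 3' minus 5' value of ACTB was 0.31 on the ERα17p array and -0.27 on the estradiol array. That of GAPDH was 0.15 and 0.06. RNA integrity may differ between these arrays, but this rests on ACTB alone.

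Lesser differences below 0 in the same comparison were a median of -0.22 for NF-kB targets (percentile 0.03; 2 of 23 at least 1.5-fold lower, ICAM1 at -0.68 and SOD2 at -0.62) and of -0.27 for oxidative stress and metal response genes (percentile 0.03; 0 of 14 past 1.5-fold, MT1F at -0.47). The last was -0.10, inside the random range, without probe sets that match several transcripts. Stress response genes had a median of -0.16 (percentile 0.47, 1 of 20 lower, CHAC1 at -0.70). That of cholesterol synthesis was -0.16 (percentile 0.83, 0 of 14 past 1.5-fold, HMGCS1 at -0.44). Without those probe sets both lay inside the range, at -0.14 and -0.10. For the stress response genes 16 members were then left, and the range reached -0.15. With histones and interferon-stimulated genes, 6 of 25 lists stood apart, 3 of them under every alternative. DNA replication and G1/S genes did not, at a median of 0.02.

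**Figure D4:**
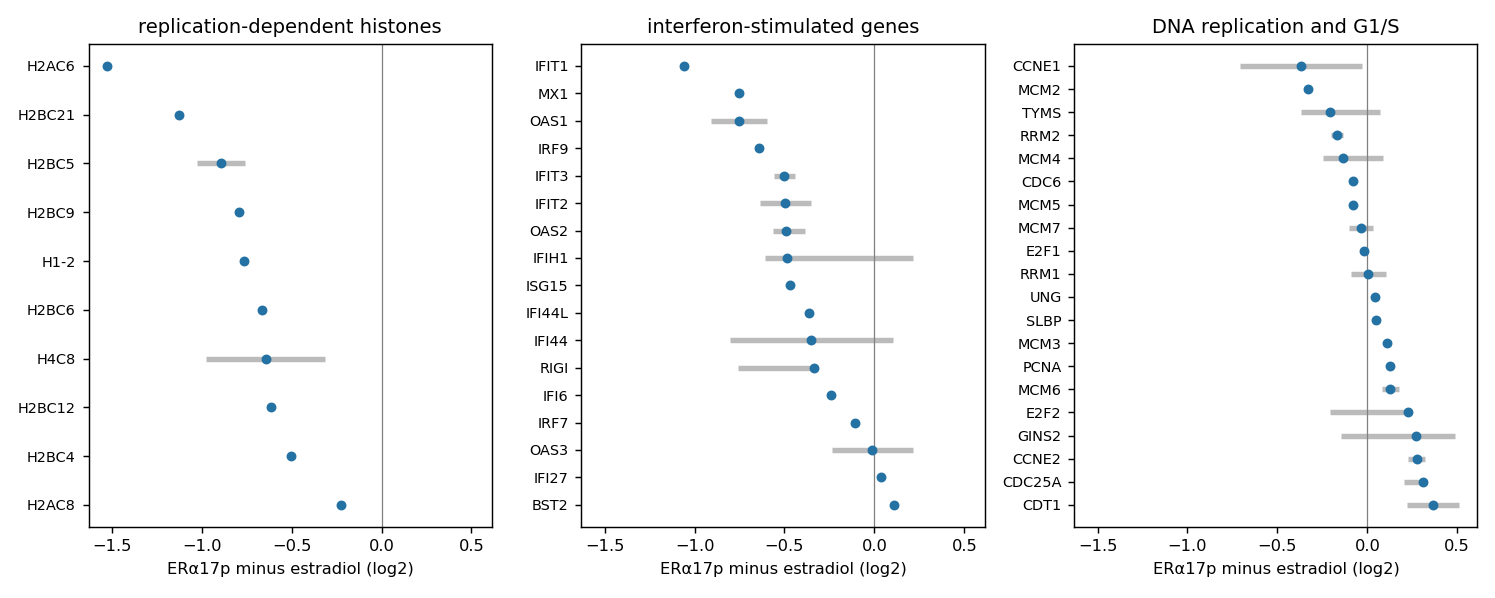
ERα17p minus estradiol (log2) for each member of 3 lists; points are the gene's median and grey bars the range of its probe sets. All 10 histones lie below 0, between -1.53 and -0.22, while DNA replication and G1/S genes scatter about a median of 0.02.

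Oestrogen receptors and classical oestrogen targets, as groups, differed little from vehicle. ESR1 was at -0.08 for estradiol and -0.14 for ERα17p against vehicle, ESR2 at -0.14 and 0.08, and the membrane receptor GPER1 at 0.28 and 0.09. Receptors and co-regulators as a list had medians of -0.08 and 0.08, with 1 of 11 higher and 1 lower in each comparison. Of 31 classical oestrogen-induced genes 4 were at least 1.5-fold higher and 2 lower for estradiol (median 0.03, percentile 62.6), and 4 higher and 1 lower for ERα17p (median 0.05, percentile 73.1). Between the treated arrays their median was -0.03, inside the random range, but -0.11 and just below it without probe sets that match several transcripts. TFF1 was 3.28 and 3.05 higher, and CA12 1.15 and 1.01 higher. Luminal epithelial markers had medians of 0.07 and 0.05, with TFF1 and AGR2 (3.32 and 3.31) high and KRT18 at -0.84 and -0.87.

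Other cell type markers and further lists lay within the random range in both comparisons with vehicle. Medians for estradiol and ERα17p were -0.03 and -0.04 for blood cell markers and 0.15 and 0.07 for fibroblast and endothelial markers. Ribosomal proteins had medians of -0.12 and -0.09, and heat shock genes of -0.22 and -0.15. Between the treated arrays heat shock genes had a median of 0.07, and of 0.22, above the range, without probe sets that match several transcripts. Interferon-stimulated genes (0.13) and oxidative stress genes (0.12) lay inside the range for ERα17p, although the first were above it with the mean of probe sets (0.32) or without probe sets that match several transcripts (0.39), as did histones (-0.14), mitosis genes (-0.12) and p53 targets (-0.09) for estradiol.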

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

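All tests in this part were chosen after the results were seen.

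Control RNAs outside the gene comparisons carried differences from the vehicle array. The labelling spikes were higher by a median of 2.03 for estradiol and 2.04 for ERα17p. The 18S ribosomal RNA was 0.67 higher for ERα17p minus vehicle, with its 3 probe sets between -0.07 and 0.75.

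The vehicle array may stand apart because it was labelled or hybridised apart from the treated arrays: its labelling spikes were lower by a median of 2.04 than the mean of the treated arrays, which differed by 0.00 from each other, though trp differed by 0.10 and 0.18 only. Degraded RNA as the cause is argued against by the 3' minus 5' values, where the vehicle array lay between the treated ones for both ACTB and GAPDH, a mean of 0.0605 from theirs. Luminal breast cells in both treated samples were checked by 17 luminal markers, with a median of 0.0566 and an upper quartile of 0.24. As a set the markers were not raised, but their SD was 1.13, and TFF1 and AGR2 were high. Expression levels are unknown, so a share of luminal cells stays open. Other differences between the cultures were not tested. A response of the genes to both treatments within 3 h stays open and cannot be told apart from the vehicle array's processing: 65.2% of the shared calls had the vehicle array away from the reference and both treated arrays near it, but the arrays behind the reference are unknown and there is 1 vehicle array. Spikes show that handling differed, not how much of any gene's difference it made.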

How the results depend on the processing

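Comparisons with the reference level, counts of genes with 2 or more probe sets in 1 direction and unmatched random lists were chosen after seeing the data. Counts below are genes higher and lower for estradiol minus vehicle, ERα17p minus vehicle and ERα17p minus estradiol, in that order. At 1.5-fold they were 2104 and 1665, 1891 and 1745, and 255 and 404; at 3-fold, 208 and 73, 182 and 71, and 0 and 2; a threshold moves a count by construction. Quantile normalisation, which gives all arrays 1 spread taken from all 3, gave 514 and 196, 397 and 295, and 81 and 181. The vehicle array's wider spread thus enters the direct counts too. Genes with 2 or more probe sets in 1 direction numbered 366 and 155, 334 and 156, and 0 and 2; fewer genes enter there. With the reference level in place of vehicle, the counts were 29 and 1 for estradiol and 3 and 10 for ERα17p; the cause was not tested. Without probe sets that match several transcripts, 14 genes were higher in the direct comparison. The correlation between treatments was 0.717 after quantile normalisation and 0.228 against the reference level.

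The other 20 alternatives of counts and correlation stayed within 1.5 times or 0.1 of the reported value. Alternatives of single genes were run only for genes named for their largest differences, not for the receptors or for genes named only as list members. The genes run had all probe sets in 1 direction, so other choices of their probe sets could not change the sign. None of those at 2-fold or more changed sign under any alternative run. Of their alternatives, 273 moved by less than the SD of the spikes and 35 by more. That SD is 1.38 and 1.46 in the comparisons with vehicle, too wide to say much about stability there, and 0.134 in the direct one. List medians moved by more than it under 4 alternatives and by less under 371; among the 4 were histones in the direct comparison, at -0.50 without probe sets that match several transcripts and -1.24 after quantile normalisation. Of 31 lists apart, 27 also were with unmatched random lists, and 2 of 124 alternatives of their medians changed sign. Under every alternative, unmatched lists included, 6 of 12, 7 of 13 and 3 of 6 lists stayed apart, and 0, 2 and 2 others came to stand apart under some; these percentiles were added after seeing the data. Centring on array medians moves nothing, since these are 0. It is nevertheless counted among the 20, 273 and 371 alternatives above, where its outcome was fixed in advance. Expression limits, the probe set of highest mean, loess on mean expression and expression-matched random lists were not run, because centred values hold no expression level. No paired analysis was possible because each group has 1 array. Signal over background is unknown, so what it limits cannot be given.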

Other observations

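The tests of explanations in the last 2 paragraphs and the genes of the next one were chosen after the results were seen; the gene lists and the alternative probe set choices had been fixed before.

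Genes with several probe sets in 1 direction add to the account. TNFSF10, the death ligand TRAIL, was 2.76 higher for estradiol and 3.06 higher for ERα17p against vehicle, with all 3 probe sets at 2.36 or more. RAB27B, a GTPase of vesicle secretion, was 2.87 and 2.58 higher, and the interferon-induced GTPase GBP1 2.45 and 2.66 higher. The translation factor EIF5A was at -1.68 and -1.79 with 3 probe sets close together, and the splicing factor TRA2A at -2.31 and -1.93, with probe sets for ERα17p from -2.81 to -0.11. Between the treatments the interferon-induced chemokine CXCL11 was at -1.17 and C11orf71 at -1.22 on the ERα17p array, and the ephrin EFNB2 and hyaluronan synthase HAS2 were 0.88 and 0.82 higher, each with 2 probe sets.

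Survival and TGF-beta lists lay inside the random range while single members were far out. Of 21 apoptosis promoters 3 were at least 1.5-fold higher and 1 lower for estradiol (median 0.03) and 4 higher and 2 lower for ERα17p (median 0.07), with the mitophagy receptor BNIP3L at 1.18 and 1.37 and the death receptor FAS at 1.15 and 0.87. Of 11 apoptosis inhibitors 2 and 3 were higher (medians -0.03 and -0.04), with the caspase inhibitor XIAP at 1.27 and 1.40. TGF-beta targets had 3 higher and 4 lower of 15 in each comparison (medians -0.14 and -0.10, but 0.06 and 0.31 without probe sets that match several transcripts, the latter above the random range), with ID3 at -2.28 for ERα17p, ID1 at -1.76 for estradiol, and SMAD7 at 1.46 for estradiol and 1.43 for ERα17p. The labelling spikes differed beside these as well, by 2.03 and 2.04, and the hybridisation spikes by -0.74 and -0.93.

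Histones were lower on the ERα17p array than on the estradiol array, by a median of -0.72. Fewer cells in S phase, with histone and G1/S transcripts lower alike, are argued against by the 20 DNA replication and G1/S genes (median 0.0233, SD 0.207 over genes). A shift in S phase of any size that G1/S genes do not show stays open. Mitosis and G2/M genes had a median of -0.10 in this comparison, with 16 below 0 and 8 above, inside the random range (percentile 4.87). Less labelling of RNA without poly(A) tails stays open: 18S ribosomal RNA, which has no tail, was 0.53 higher, but this is 1 transcript. Whether the histone transcripts read here lacked tails is not known either. Cross-hybridising probe sets that read 1 signal cannot be told apart from a difference in several genes, since the 5 probe sets without the multi-transcript suffixes had a median of -0.50, all below 0, with an SD of 0.220. A difference between the peptide and the hormone is a further, untested explanation.

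Interferon-stimulated genes were lower on the ERα17p array than on the estradiol array as well, by a median of -0.47, and stayed apart under all 4 alternatives (-0.54 to -0.42). Noise of single probe sets no larger than in other genes is argued against by 10000 random lists, whose medians ran from -0.25 to 0.25 (percentile 0). Larger noise in these genes than in others stays open, with 15 of 17 lower (88.2%): all sign assignments to their own differences were tried with 3 statistics, and as large a mean arose in 0.0137%, a median in 0.391% and a count of 1 sign in 0.235%, so 1 of 3 was under the 0.2% that 25 lists call for. A processing difference between the treated arrays cannot be told apart from a treatment difference with 1 array each; the spikes differed by a median of -0.10. An effect of either agent on these genes was not tested.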
